A study of Mus musculus with 32 samples.

How the data were processed

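Gene expression was measured in total RNA of the mouse cell line UB/OC-1 on 2 oligonucleotide array designs, a and b, with 16 arrays each. The deposited values are array intensities, scaled by the authors: they are linear whole numbers, 22.9% of them negative on design a and 33% on design b, and the trimmed mean of every array (2% left out at each end) lay between 300.4 and 300.8. Because these trimmed means differed by less than 5%, the values were used as deposited. The software and the background method behind them are not given in the sources used here. No column of values was left unused. Labels gave the experiment (A or B), the day and the temperature (33 °C at day 0, 39 °C later).

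Design a held 6584 probe sets and design b 6595, of which 61 per design were controls and left out of all tests. One gene symbol was given for 5541 and 2001 of them, several for 197 and 27, and none for 785 and 4506. Symbols came from the platform annotation, and an annotation of mouse genes was used for names alone, with no positions. Probe sets with names ending in f_at are shared by members of a gene family, so the gene they report is uncertain. In the comparisons described here this holds for probe sets of Ass1, Mgp, Slc25a5, Top2a, Grn, Ctsa, Psap, Serpinh1, Cdkn1a, B2m, Psmb9, Rpl29, Rpl12, Rpl8, Rpl10a, Tmsb10, Cryab, Cct3, Cct4, Fn1, Cycs, Ldhb and Rps26, and for that of Rrm2 late against early.

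Values below a floor were set to it before taking log2. The floor was the 75th percentile of the absolute size of the negative values of a design, 141 for a and 198 for b. A probe set was tested if it was above the floor on at least 2 of 16 arrays, which left 4294 on design a and 3432 on design b, 7726 in total. Where every array of a group was at the floor, the fold is given as a lower bound. Where some arrays of the dimmer group were at the floor, the fold is a low estimate. Arrays tied at the floor show no spread, so the p-values of such probe sets can be too small.

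Models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust), for each design separately, with Benjamini-Hochberg adjustment over both designs together and a threshold of 0.05 for adjusted p. The phases were day 0 (n = 2), early (days 1 to 3, n = 4), middle (days 4 to 7, n = 5) and late (days 8 to 14, n = 5), and 3 contrasts between them shared 1 estimate of the spread with 12 residual degrees of freedom. Days act as the samples of a phase, so the spread includes change within it. The time course was an F-test of a natural spline in day with 3 degrees of freedom. Days 2, 4 and 9 were compared with day 0 in a fit of the 8 arrays of the 4 days with both experiments, with 4 residual degrees of freedom. All tests were two-sided. Phases, tests, lists and the rule for named genes were fixed before the data were examined.

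The labels share an experiment between days, and the differences between experiments A and B correlated across probe sets between days (r from 0.33 to 0.70 over 6 pairs of days), so experiment pairs the samples. Results with experiment as a block are given beside those without for the counts, and where the call of a list or of a named gene between phases changes. Experiment B has 1 array in each phase, so the phases were not tested within it, and its list medians are given as values. It makes up a larger share of day 0 than of the later phases. Without the block, differences between the experiments can thus enter the contrasts with day 0. A list median over all arrays can then lie outside those of both experiments. Among others, it did so late for otic and inner ear development genes (0.74, against 0.32 in experiment A and 0.70 in experiment B). Covariates for the noise level of each array (the 75th percentile of the absolute size of its negative values) and for its Gapdh control ratio, and a fit without day 6 of experiment A, were added after seeing the data.

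A set of 24 gene lists was tested with camera (preset correlation 0.01, lists of at least 5 probe sets) in the 3 phase comparisons, 72 tests adjusted together. They were hair cell, otic and inner ear development, supporting cell, Notch pathway, otic neuron, cell cycle and DNA replication, CDK inhibitors and p53 targets, apoptosis, heat shock and protein folding, endoplasmic reticulum stress, interferon and MHC class I, extracellular matrix, epithelial, mesenchymal cell, skeletal and cardiac muscle, melanocyte and glia, macrophage and blood cell, endothelial cell, ribosomal protein, oxidative phosphorylation, glycolysis, cholesterol synthesis and lysosome, and 1 list that is not reported here. In all, 20 of 72 tests passed, 19 with experiment as a block. With a correlation estimated from the data 7 passed, among them cell cycle, interferon and lysosome genes early and late against day 0. Members were also counted after adjustment over the list alone.

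Named genes were, for each phase comparison, the 10 largest increases and decreases among probe sets with 1 symbol, an adjusted p under 0.05 and no overlap between the arrays of the phases, the 4 genes with the smallest p in each list past the threshold, and 12 genes fixed beforehand. For the time course they were the 10 genes with the smallest p, and for day 9 the 5 largest changes in each direction. Where a gene had several probe sets, the one with the larger change was named among the largest changes, and elsewhere the one with the smallest p. Some further members of lists are named beside their list's count.

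Alternatives were quantile normalization, floors lowered or raised by a log2 of 1, no filter, a filter on 8 arrays, an arcsinh scale, experiment as a block, experiment A only, adjustment within each design, eBayes without trend and robust, spline degrees of freedom, other phase limits, 1 probe set per gene and leaving out each culture in turn. The fits were tested on simulated data with 200 of 7726 probe sets changed. At a log2 change of 1, they recovered 26% for the time course, 28% for early against day 0, 26% for late against day 0, 38% for late against early and 3% for day 9 against day 0. At a log2 change of 2, they recovered 75%, 69%, 74%, 88% and 23%, with 1, 3, 8, 5 and 0 false calls in these fits. The simulated values had no floor and no difference shared by the arrays of an experiment. Recovery and false calls may therefore differ in the real data. A simulated shift of 0.5 in the lysosome list was found at an adjusted p of 4.63e-14, and 0 other list tests passed. The simulated probe sets varied independently of each other. This run therefore cannot show how often camera gives false list calls among correlated genes. The number of arrays limits the precision of every estimate.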

Results

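The cells were UB/OC-1, a conditionally immortal mouse line derived from the developing organ of Corti, the sensory epithelium of the cochlea. At 33 °C (day 0) the line is undifferentiated by its labels, and at 39 °C it is under the conditions that the labels name as differentiating. Total RNA was measured on a pair of oligonucleotide array designs, called a and b, which gave 32 samples, 16 for each design. Experiment A covered 12 days (days 0 to 9, 11 and 14) and experiment B covered 4 (days 0, 2, 4 and 9). Days were grouped into day 0 (n = 2 arrays per design), early (days 1 to 3, n = 4), middle (days 4 to 7, n = 5) and late (days 8 to 14, n = 5). On each array, 44.1% to 50.7% of the probe sets of design a and 30.8% to 40.4% of those of design b were above the floor. The number of arrays limits the precision, and all p-values measure only the spread between these samples. Changes are log2 differences with their standard error (SE).

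The first comparison, early against day 0, asks what happened in the first days after the temperature shift. Genes of the interferon response held 6 of the 10 largest decreases. Iigp1, an interferon-inducible GTPase, fell by 5.91 ± 0.46 (SE, n = 4 against 2), 59.9-fold, from a mean intensity of 13800 to 231 (adjusted p = 1.87e-07). Igtp, a GTPase of the same family, was 17.1-fold lower (adjusted p = 4.8e-05), and Psmb10, a subunit of the immunoproteasome, was at least 16.9-fold lower, since every later array was at the floor (adjusted p = 1.63e-08). Among the increases, Crip2, which encodes a LIM-domain protein, rose 15.4-fold (3.94 ± 0.38, adjusted p = 5.47e-06), and Synpo, which encodes an actin-associated protein, rose at least 9.79-fold from the floor (adjusted p = 5.37e-05). Col6a1, a chain of collagen VI, rose at least 8.74-fold and Igfbp2, a binding protein of insulin-like growth factors, at least 7.86-fold.

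The other largest increases were those of Maged2 (6.92-fold), Ube2h (6.49-fold), Ass1 (at least 5.47-fold), Agrn (5.23-fold), Mgp (at least 5.21-fold) and Pltp (at least 4.9-fold). Ube2h encodes a ubiquitin-conjugating enzyme, Ass1 argininosuccinate synthase, Agrn the proteoglycan agrin and Mgp matrix Gla protein. The rise of Mgp passed on only 1 of its 2 probe sets. The other largest decreases were those of the guanylate-binding protein genes Gbp7 (8.97-fold), Gbp2 (8.89-fold) and Gbp3 (at least 7.96-fold), and of Hmga2 (6.75-fold), an architectural chromatin protein of proliferating embryonic cells. They were joined by those of Ccn2 (6.43-fold), a matrix-associated growth factor, Gar1 (5.42-fold), a nucleolar protein, and Slc25a5 (5.19-fold), a mitochondrial ADP/ATP carrier. Leaving out day 0 of experiment B ended the calls of Igfbp2 (adjusted p = 0.077), Maged2 (0.0506), Mgp (0.0779), Ccn2 (0.0716), Gar1 (0.198) and Slc25a5 (0.146), and leaving out day 0 of experiment A ended that of Maged2 (0.0662). Iigp1 was 32.2-fold lower without day 0 of experiment A and 111-fold lower without day 0 of experiment B, and Gbp7 15.5-fold and 5.18-fold. In experiment A alone, the calls of Igfbp2 (adjusted p = 0.137), Mgp (0.0644), Pltp (0.0525), Ccn2 (0.0781) and Slc25a5 (0.101) ended. With the higher floor those of Igfbp2 (adjusted p = 0.0684), Mgp (0.11) and Pltp (0.0824) ended, and with the lower floor that of Gar1 (0.056).

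Genes of the cell cycle and DNA replication fell together in the early phase. Of 53 probe sets, 8 fell, 0 rose and 45 did not pass, with 17 lower when adjusted over the list alone. The median change was -0.88 (-0.92 in experiment A, -0.74 in experiment B; camera adjusted p = 3.27e-18). Tk1, thymidine kinase of the salvage pathway, was 3.96-fold lower, Ezh2, a histone methyltransferase, 2.4-fold lower, the transcription factor gene Mybl2 at least 1.49-fold lower, and Top2a, a topoisomerase of dividing cells, 2.66-fold lower. The call of Top2a ended without day 3 of experiment A (adjusted p = 0.0611) and without day 0 of experiment B (0.117), in experiment A alone (0.254), with the lower floor (0.102), on the arcsinh scale (0.231) and with early as days 1 and 2 (0.058). That of Ezh2 ended with the lower floor (adjusted p = 0.0988) and that of Mybl2 on the arcsinh scale (0.279). Mki67, a marker of dividing cells, had a change of -0.90 ± 0.31 (adjusted p = 0.15; 0.0396 with eBayes without trend and robust), and Pcna, the sliding clamp of DNA polymerase, one of -1 ± 0.42 (adjusted p = 0.277), so neither passed.

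Interferon and MHC class I genes had 12 of 46 probe sets lower, 0 higher and 34 that did not pass, with 19 lower when adjusted over the list alone. Their median change was -0.57 (-0.92 in experiment A, -0.48 in experiment B; camera adjusted p = 5.77e-15), and B2m, the light chain of MHC class I molecules, had a change of 0.35 ± 0.41 (adjusted p = 0.891). Lysosome genes rose, with 4 of 33 probe sets higher, 0 lower and 29 that did not pass (12 higher when adjusted over the list alone). The list had a median of 0.75 (0.78 in experiment A, 1.00 in experiment B; camera adjusted p = 2.96e-10). The 4 that rose included 2 of 3 probe sets of Grn, the progranulin gene (4.51-fold for the better one). The others were 1 of 2 probe sets of Ctsa, a lysosomal carboxypeptidase (4.65-fold), and that of Ctsd, the protease cathepsin D (3.98-fold). Psap, the precursor of the saposins, had a change of 0.87 ± 0.27 (adjusted p = 0.0842; 0.0248 with experiment as a block, 0.0386 with eBayes without trend and robust, 0.0412 with the noise covariate). Ctsd lost its call without day 0 of experiment A (adjusted p = 0.056) or of experiment B (0.0571), and Ctsa without day 0 of experiment B (0.0543), in experiment A alone (0.117) and with the higher floor (0.0645).

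CDK inhibitor and p53 target genes had 3 of 24 probe sets higher, 0 lower and 21 that did not pass, and 3 higher when adjusted over the list alone (median 0.77; 0.56 in experiment A, 1.23 in experiment B; camera adjusted p = 5.21e-05; adjusted p = 0.159 with an estimated correlation). Mdm2, the ubiquitin ligase of p53, rose 3.13-fold and Ccng1, a p53-induced cyclin, 4.28-fold. Fas, a death receptor, had a change of 1.19 ± 0.41 (adjusted p = 0.136), Plk2 one of -1.15 ± 0.47 (adjusted p = 0.254), Cdkn1a, the CDK inhibitor p21, one of 1.09 ± 0.62 (adjusted p = 0.537), and Cdkn1b, the CDK inhibitor p27, one of 0.82 ± 0.48 (adjusted p = 0.563). Mdm2 lost its call without day 0 of experiment B (adjusted p = 0.228) and in experiment A alone (0.268), and Ccng1 with early as days 1 and 2 (0.0606) and without day 0 (0.286, 2.64-fold) or day 3 (0.0605) of experiment A. Without day 0 of experiment B its fold was 6.94. Extracellular matrix genes had 5 of 54 probe sets higher, 1 lower and 48 that did not pass (14 higher and 2 lower when adjusted over the list alone). Their median was 0.37 (0.30 in experiment A, 0.12 in experiment B; camera adjusted p = 0.000337; adjusted p = 0.174 with an estimated correlation), and this call ended without day 0 of experiment B (adjusted p = 0.0635). Both probe sets of Serpinh1, a collagen chaperone, were among those that rose (3.11-fold for the better one), and Ccn2 was the member that fell.

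Across all genes, 270 of 7726 probe sets changed early, 112 higher and 158 lower, and 1009 had an unadjusted p under 0.05. With experiment as a block 469 passed, in experiment A alone 173, with early limited to days 1 and 2 172, and with the noise level of each array as a covariate 451, a setting chosen after seeing the data. The balance of directions depended on the settings: 120 were higher and 102 lower with the lower floor, 113 and 95 with the filter on 8 arrays, and 87 and 220 with the higher floor. The count was 126 without day 0 of experiment B and 172 without day 3 of experiment A. With only 2 arrays at day 0, a single day 0 culture carried much weight in these changes.

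The comparison of the late phase with day 0 sets the end of the time course against undifferentiated cells. Dcn, which encodes the matrix proteoglycan decorin, rose at least 72.3-fold from the floor (6.18 ± 0.89, n = 5 against 2, adjusted p = 0.000173), to a mean intensity of 14300. The array of experiment B at day 9 stood below the other late arrays for Dcn, at a log2 intensity of 12.3 against 14 for the nearest. Aldh1a1, a retinaldehyde dehydrogenase that makes retinoic acid, rose 27.2-fold (4.77 ± 0.48, adjusted p = 6.33e-06), and Gas1, a membrane protein first known from growth-arrested cells, rose 22.9-fold (4.52 ± 0.55, adjusted p = 3.69e-05). Iigp1 fell by 6.49 ± 0.44, at least 90.1-fold since 3 of 5 late arrays were at the floor (adjusted p = 2.75e-08), and Hmga2 was at least 9.26-fold lower (adjusted p = 3.4e-05). Acta2, smooth muscle actin, was at least 8.94-fold lower, and Krt18, a keratin of simple epithelia, was 6.23-fold lower (adjusted p = 0.000134).

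The other largest increases were those of the collagen VI chain genes Col6a1 (at least 22.1-fold) and Col6a2 (10.8-fold), Crip2 (15.6-fold), the glutathione transferase gene Gstm2 (9.49-fold), the lipoprotein receptor gene Vldlr (at least 9.38-fold, from day 0 arrays at or next to the floor), the heparan sulfate proteoglycan gene Sdc2 (8.49-fold) and Synpo (at least 8.42-fold). The other largest decreases were those of Igtp (18.6-fold), the immunoproteasome genes Psmb10 (at least 16.9-fold), Psmb9 (at least 10.7-fold) and Psmb8 (8.65-fold), and Gbp2 (9.59-fold), Gbp7 (9.28-fold) and Gbp3 (at least 7.96-fold). Vim, the intermediate filament vimentin, was 3.14-fold lower (adjusted p = 0.0243), and Mki67 was 2.59-fold lower (adjusted p = 0.00557). Pcna had a change of -1.17 ± 0.41 that did not pass (adjusted p = 0.0799; 0.0447 with experiment as a block), and its array at day 11 of experiment A stood apart at a log2 intensity of 8.45. Cdkn1a had a change of 0.50 ± 0.60 (adjusted p = 0.671), with the day 9 array of experiment B apart at 9.86, and B2m one of 0.51 ± 0.40 (adjusted p = 0.507). Vim lost its call without day 0 (adjusted p = 0.133) or day 14 (0.0541) of experiment A or day 0 of experiment B (0.126), and Mki67 without day 0 of experiment A (0.0599). Vim also lost it with no filter (adjusted p = 0.0537) and with the noise level (0.1) or the Gapdh control ratio (0.0875) as a covariate. Without day 0 of experiment A and of experiment B in turn, Iigp1 was 48.5-fold and 167-fold, Gbp7 16.1-fold and 5.36-fold, and Acta2 at least 5.06-fold and 15.8-fold lower.

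In the cell cycle and DNA replication list, 28 of 53 probe sets were lower late than at day 0, 0 were higher and 25 did not pass (35 lower when adjusted over the list alone). Cell cycle genes had a median of -1.17 (-1.12 in experiment A, -1.06 in experiment B; camera adjusted p = 1.82e-21). Rrm2, a subunit of ribonucleotide reductase, was at least 6.76-fold lower, Tk1 4.5-fold, Ezh2 at least 2.56-fold and Mybl2 at least 1.49-fold lower. Of 46 interferon and MHC class I probe sets 15 fell, 2 rose and 29 did not pass (18 lower and 2 higher when adjusted over the list alone). This list had a median of -0.78 (-1.05 in experiment A, -0.27 in experiment B; camera adjusted p = 1.46e-10). The probe sets that rose were those of Ifit3, an interferon-induced protein (at least 3.76-fold), and of Ifngr1, a chain of the interferon gamma receptor (at least 2.4-fold). Lysosome genes had 10 of 33 probe sets higher, 0 lower and 23 that did not pass (14 higher when adjusted over the list alone). They had a median of 0.85 (0.77 in experiment A, 1.23 in experiment B; camera adjusted p = 1.44e-07). Ctsd rose 5.93-fold, Hexa, a subunit of hexosaminidase, 5.66-fold, Ctsa 4.66-fold and Psap 2.57-fold.

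Among genes of otic and inner ear development, 6 of 20 probe sets rose late, 0 fell and 14 did not pass (7 higher when adjusted over the list alone; median 0.74; 0.32 in experiment A, 0.70 in experiment B; camera adjusted p = 0.00269; adjusted p = 0.199 with an estimated correlation). Bmp4, a signalling ligand, rose 4.31-fold, Id2, an inhibitor of helix-loop-helix transcription factors, 5.47-fold, Zfpm1, a cofactor of GATA factors, 5.28-fold, and Gata3, a transcription factor of the developing ear, at least 3.01-fold. Gata3 lost its call in 5 of 16 fits that left out 1 culture, with adjusted p = 0.187 without day 0 of experiment B, 0.127, 0.0622, 0.068 and 0.0513 without days 0, 8, 9 and 14 of experiment A. It also lost its call in experiment A alone (adjusted p = 0.175), after quantile normalization (0.112), with the lower (0.0561) and the higher floor (0.182), with no filter (0.0623), on the arcsinh scale (0.0587) and with late as days 9 to 14 (0.0624). Zfpm1 lost its call without day 0 of experiment A (adjusted p = 0.0506).

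Ribosomal protein genes had 9 of 45 probe sets lower, 0 higher and 36 that did not pass (14 lower when adjusted over the list alone). Ribosomal genes had a median of -0.45 (-0.71 in experiment A, -0.27 in experiment B; camera adjusted p = 5.45e-07; adjusted p = 0.199 with an estimated correlation). Rpl29 was 2.53-fold, Rpl12 2.74-fold, Rpl8 2.86-fold and Rpl10a 1.87-fold lower. Rpl8 lost its call without day 0 of experiment B (adjusted p = 0.0635), and Rpl10a without day 0 of experiment B (0.0654) or without day 0 (0.179) or day 14 (0.0519) of experiment A, and in experiment A alone (0.0658).

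Heat shock and protein folding genes went both ways, with 11 of 42 probe sets lower, 6 higher and 25 that did not pass (12 lower and 7 higher when adjusted over the list alone; median -0.39; -0.12 in experiment A, -0.30 in experiment B; camera adjusted p = 0.0274; adjusted p = 0.199 with an estimated correlation). The list passed in neither experiment A alone (adjusted p = 0.33) nor the fit with experiment as a block (0.0666), nor without day 11 of experiment A (0.0761) or day 0 of experiment B (0.385). It did not pass after quantile normalization (adjusted p = 0.0814), with 1 probe set per gene (0.0902), or with the noise level (0.278) or the Gapdh control ratio (0.079) as a covariate. Of those that fell, Cct3, a subunit of the cytosolic chaperonin, was 3.74-fold and Hspd1, the mitochondrial chaperonin, 2.45-fold lower, while Cryab, a small heat shock protein, rose 2.64-fold. One probe set of Hspa4 fell 4.16-fold and the other rose 2.6-fold. Cct3 lost its call without day 0 of experiment B (adjusted p = 0.069) and Hspd1 without day 0 of experiment A (0.111), and the fall of Hspa4 did not pass in experiment A alone (0.0512). CDK inhibitor and p53 target genes had 3 of 24 probe sets higher, 1 lower and 20 that did not pass (3 higher and 1 lower when adjusted over the list alone; median 0.62; 0.32 in experiment A, 0.91 in experiment B; camera adjusted p = 0.0274; adjusted p = 0.472 with an estimated correlation). The call of this list ended in experiment A alone (adjusted p = 0.09), without day 0 of experiment A (0.126), without day 9 of experiment B (0.111), with the higher floor (0.117) and with the filter on 8 arrays (0.0705). Gadd45a, a growth arrest and DNA damage gene, rose at least 5.04-fold, Cdkn1b 3.02-fold and Ccng1 2.91-fold, and Plk2 was 3.07-fold lower. The rise of Cdkn1b passed on only 1 of its 3 probe sets. Cdkn1b lost its call in 5 of 16 fits that left out 1 culture (largest adjusted p = 0.272 without day 0 of experiment A), Ccng1 in 8 (0.422 without day 0 of experiment A, 1.79-fold, against 4.71-fold without day 0 of experiment B) and Plk2 in 3 (0.353 without day 0 of experiment B). Plk2 also lost it in experiment A alone (adjusted p = 0.0594), with no filter (0.062) and with late as days 9 to 14 (0.0519). Cdkn1b lost it after quantile normalization (adjusted p = 0.0597), with the higher floor (0.0582), with no filter (0.0871), on the arcsinh scale (0.0512) and with late as days 9 to 14 (0.0688). Under the same settings the adjusted p of Ccng1 was 0.0762, 0.0511, 0.0913, 0.0677 and 0.0803, and it was 0.0516 with the lower floor and 0.0581 with eBayes without trend and robust.

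Extracellular matrix genes as a list did not pass late (camera adjusted p = 0.326, median 0.40), with 10 of 54 probe sets higher, 8 lower and 36 that did not pass, and 11 higher and 9 lower when adjusted over the list alone. In all, 844 of 7726 probe sets changed late, 374 higher and 470 lower, with 1731 at an unadjusted p under 0.05. With experiment as a block 1117 passed, 527 higher and 590 lower. In experiment A alone 555 passed, and without day 0 of experiment B 402. With the filter on 8 arrays 384 were higher and 376 lower. The median change of all probe sets was 0.11 as deposited and 0.04 after quantile normalization, where 327 were higher and 495 lower.

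**Figure D1:**
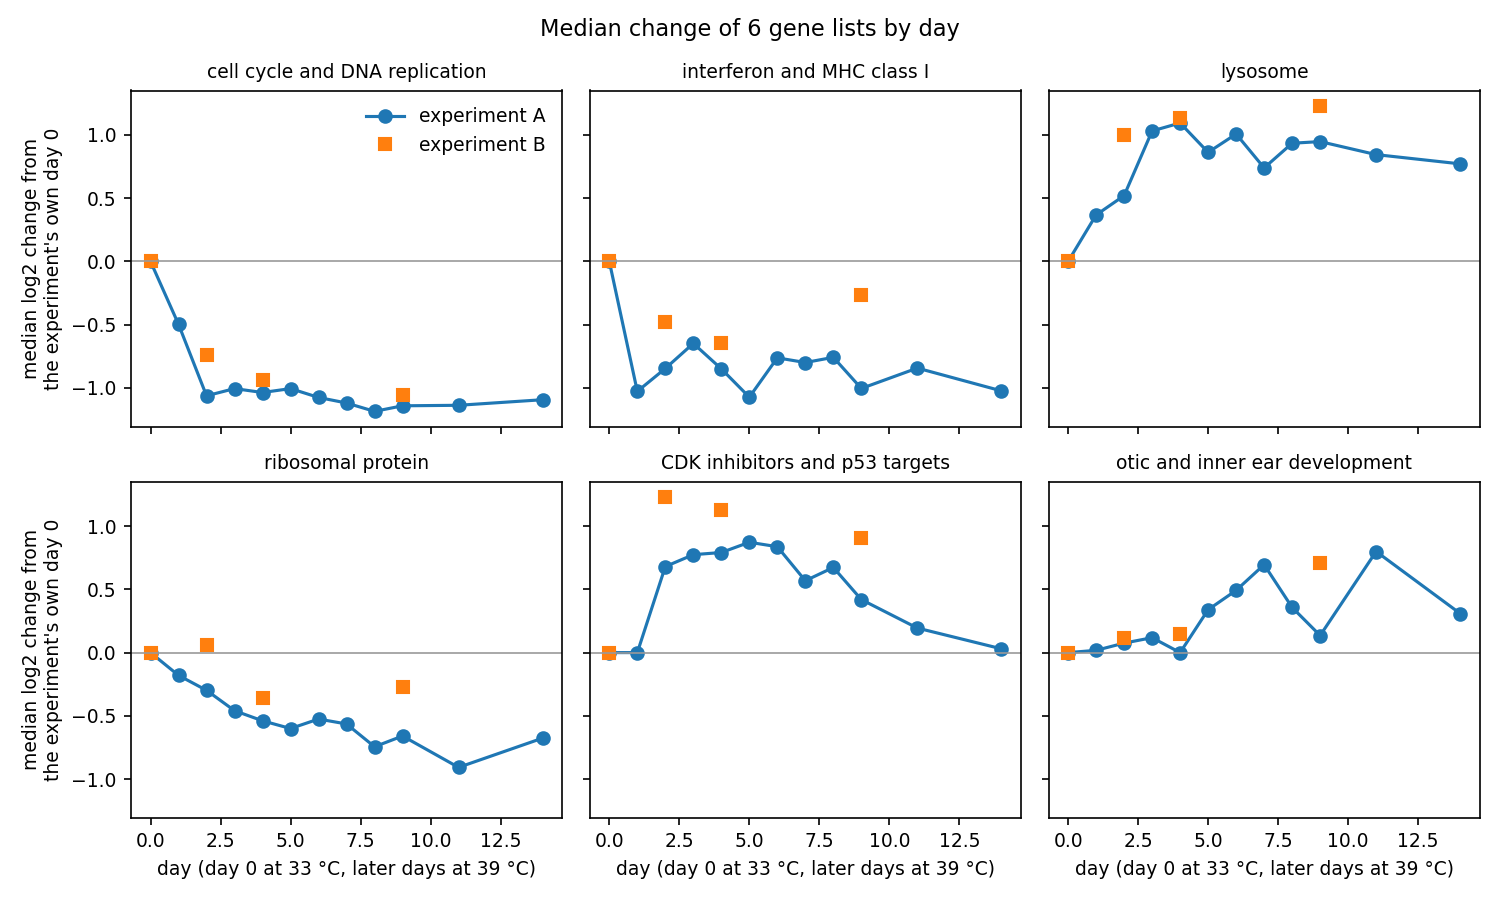
Median log2 change of the probe sets of 6 gene lists (vertical axis) against the day (horizontal axis), each array relative to day 0 of its own experiment, with a line for experiment A and squares for experiment B. The cell cycle list lies at -1.06 on day 2 of experiment A and between -1.19 and -1.01 on every later day of that experiment.

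The comparison of the late with the early phase covers the time at 39 °C, with temperature held constant. Aldh1a1 rose 6.43-fold (2.69 ± 0.39, n = 5 against 4, adjusted p = 0.00255), Scg2, a granin of secretory vesicles, 6.19-fold (2.63 ± 0.38, adjusted p = 0.00255), Gsta3, a glutathione transferase, at least 5.78-fold and Bmp4 3.57-fold (1.84 ± 0.24, adjusted p = 0.00111). Igfbp7, a secreted binding protein, fell by 3.03 ± 0.50, 8.14-fold (adjusted p = 0.00474), and Timp1, an inhibitor of metalloproteinases, was 5.25-fold lower. Fn1, fibronectin, was 3.73-fold lower (adjusted p = 0.00405) and Krt18 3.61-fold lower (adjusted p = 0.00405). Other increases were those of Gas1 (5.18-fold), Vldlr (4.38-fold), the transcription factor gene Atf5 (4.03-fold), the ceruloplasmin gene Cp (3.78-fold), the mannosidase gene Man1a (3.59-fold) and Ifit3 (3.54-fold). Other decreases were those of Rps26 (3.36-fold), Rrm1 (3.21-fold), Tmsb10 (3.21-fold), the follistatin gene Fst (3.09-fold), Rpl13a (3.05-fold) and Acta2 (at least 2.94-fold).

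Rrm2 lost its call in 11 of 16 fits that left out 1 culture (largest adjusted p = 0.228), Acta2 in 10 (0.184), Rpl10a in 10 (0.14), Ube2c in 10 (0.198), Dcn in 6 (0.0825), Rpl13a in 6 (0.156) and Rps26 in 6 (0.184), in each case with the largest value without day 1 of experiment A. Atf5 (largest adjusted p = 0.0643 without day 2 of experiment B) and Cp (0.059 without day 2 of experiment A) lost it in 4, Ifit3 (0.059 without day 2 of experiment A) and Vldlr (0.0641 without day 1 of experiment A) in 2, and Fst (0.0555) and Gas1 (0.0526) in 1, that without day 2 of experiment A. In experiment A alone, calls ended for Gas1 (adjusted p = 0.0569), Vldlr (0.0949), Cp (0.054), Man1a (0.0528), Ifit3 (0.127), Timp1 (0.0565), Krt18 (0.0528), Rps26 (0.142), Rrm1 (0.0764), Fst (0.101), Rpl13a (0.114), Rpl10a (0.101), Ube2c (0.15), Rrm2 (0.0565) and Dcn (0.101). With no filter they ended for Atf5 (adjusted p = 0.0638), Rps26 (0.129), Rpl13a (0.0835), Acta2 (0.0822), Rpl10a (0.0822), Ube2c (0.0925), Rrm2 (0.13) and Dcn (0.197). With the higher floor they ended for Atf5 (adjusted p = 0.0628), Ifit3 (0.0544) and Acta2 (0.468). Narrower phases (days 1 and 2 against days 9 to 14) ended those of Atf5 (adjusted p = 0.094) and Ifit3 (0.0718). Rrm2 also lost its call with the lower floor (adjusted p = 0.0558) and on the arcsinh scale (0.0541), and Rpl12 after quantile normalization (0.0551). Rps26 (adjusted p = 0.0558) and Dcn (0.0566) lost theirs with eBayes without trend and robust.

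Ribosomal protein genes had 4 of 45 probe sets lower late than early, 0 higher and 41 that did not pass (9 lower when adjusted over the list alone). As a list they had a median of -0.43 (-0.44 in experiment A, -0.46 in experiment B; camera adjusted p = 5.47e-13; adjusted p = 0.0758 with an estimated correlation). They were Rpl12 (2.12-fold), Rpl13a, Rps26 and Rpl10a (1.83-fold), of which Rpl10a, Rpl13a and Rps26 lost their calls without day 1 of experiment A (adjusted p = 0.14, 0.156 and 0.184).

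Cell cycle and DNA replication genes had 3 of 53 probe sets lower late than early, 0 higher and 50 that did not pass (6 lower when adjusted over the list alone). All 53 together had a median of -0.28 (-0.30 in experiment A, -0.26 in experiment B; camera adjusted p = 9.51e-09; adjusted p = 0.115 with an estimated correlation). They were Rrm1, Rrm2 (2.7-fold) and Ube2c, a ubiquitin-conjugating enzyme of mitosis (2.49-fold), and the calls of Rrm2 and Ube2c ended without day 1 of experiment A (adjusted p = 0.228 and 0.198). Tyms, thymidylate synthase, had a change of -0.87 ± 0.28 (adjusted p = 0.184). Otic and inner ear development genes had 1 of 20 probe sets higher, that of Bmp4, 0 lower and 19 that did not pass (3 higher when adjusted over the list alone). All 20 together had a median of 0.46 (0.43 in experiment A, 0.41 in experiment B; camera adjusted p = 0.00256; adjusted p = 0.199 with an estimated correlation). Id2 had a change of 1.20 ± 0.31 (adjusted p = 0.0768; 0.0235 with experiment as a block, 0.0201 with the noise covariate), Zfpm1 one of 1.28 ± 0.41 (adjusted p = 0.184) and Gata3 one of 1.05 ± 0.37 (adjusted p = 0.249).

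Extracellular matrix genes had 4 of 54 probe sets lower and 1 higher, with 49 that did not pass (9 lower and 3 higher when adjusted over the list alone). The median was 0.00 (0.02 in experiment A, -0.01 in experiment B) and the mean -0.12, and the camera test was for a decrease (adjusted p = 0.0232; adjusted p = 0.409 with an estimated correlation). Both Fn1 probe sets, Timp1 and Igfbp7 fell, while Dcn rose 10.3-fold (3.37 ± 0.72). This call ended in experiment A alone (adjusted p = 0.117), without day 3 of experiment A (0.249), without day 9 of experiment B (0.136), on the arcsinh scale (0.0506) and with 1 probe set per gene (0.12). Dcn rose less without day 1 of experiment A, 5.38-fold (adjusted p = 0.0825), and more without day 3, 17.5-fold. None of the 42 heat shock and protein folding probe sets passed, with 0 when adjusted over the list alone. Their median was -0.17 (-0.15 in experiment A, -0.16 in experiment B; camera adjusted p = 0.00319; adjusted p = 0.115 with an estimated correlation). Cct4 had a change of -0.68 ± 0.21 (adjusted p = 0.172), Dnajc3 one of 1.11 ± 0.35 (adjusted p = 0.184; 0.00865 with experiment as a block, 0.0275 with the noise and 0.0341 with the Gapdh covariate), Serpinh1 one of -0.59 ± 0.21 (adjusted p = 0.241) and Hspa14 one of -0.75 ± 0.29 (adjusted p = 0.321). The call of this list ended in experiment A alone (adjusted p = 0.0563), without day 2 of experiment B (0.0585), with the noise level as a covariate (0.142) and with 1 probe set per gene (0.0775).

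Of 37 oxidative phosphorylation probe sets 0 passed late against early, over all genes or over the list alone (median -0.06; -0.04 in experiment A, -0.14 in experiment B; camera adjusted p = 0.0174; adjusted p = 0.409 with an estimated correlation). Uqcrfs1 (-1.19 ± 0.46, adjusted p = 0.328), Uqcrc1 (-1.11 ± 0.43, adjusted p = 0.331), Atp5b (-0.40 ± 0.19, adjusted p = 0.498) and Ndufa1 (0.61 ± 0.30, adjusted p = 0.505) had its smallest p-values. The call of this list ended in experiment A alone (adjusted p = 0.168), without days 3 (0.0903), 11 (0.179) or 14 (0.0598) of experiment A and without day 2 of experiment B (0.157). It also ended after quantile normalization (adjusted p = 0.128), with the lower floor (0.118), on the arcsinh scale (0.06), and with the noise level (0.278) or the Gapdh control ratio (0.0768) as a covariate.

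Late against early, 76 of 7726 probe sets changed, 33 higher and 43 lower, and 773 had an unadjusted p under 0.05. The count was 184 with experiment as a block, 31 in experiment A alone and 40 with no filter on dim probe sets, and 166 and 141 with the noise level or the Gapdh control ratio of each array as a covariate, both chosen after seeing the data. With the noise covariate 85 were higher and 81 lower. Without day 1, 2, 3, 9, 11 or 14 of experiment A it was 32, 30, 118, 46, 42 or 39, and without day 2 of experiment B 41. Of the genes fixed beforehand, Vim (-0.80 ± 0.36, adjusted p = 0.464), Mki67 (-0.47 ± 0.24, adjusted p = 0.561), Cdkn1b (0.77 ± 0.38, adjusted p = 0.511; 0.0213 with the noise covariate), Cdkn1a (-0.59 ± 0.48, adjusted p = 0.772), Pcna (-0.17 ± 0.33, adjusted p = 0.932) and B2m (0.16 ± 0.32, adjusted p = 0.932) did not pass.

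Hair cell genes did not pass as a list in any comparison, with 0 of 10 probe sets past in each of the 3 and a smallest camera adjusted p of 0.689. Only 8 of the 36 genes of this list had a tested probe set, 7 of 27 for supporting cell and 9 of 27 for otic neuron genes. These tests therefore cannot show that such genes stayed unchanged. Myo7a was also dim, at 141 to 449 over all arrays against a floor of 141. Myo7a, the myosin of hair cell stereocilia, had changes of 0.15 ± 0.40 early against day 0 (adjusted p = 0.99), 0.41 ± 0.39 late against day 0 (adjusted p = 0.589) and 0.26 ± 0.31 late against early (adjusted p = 0.864). Gata3 had a change of 0.53 ± 0.48 early against day 0 (adjusted p = 0.809), Krt18 one of -0.79 ± 0.38 (adjusted p = 0.407) and Vim one of -0.85 ± 0.47 (adjusted p = 0.509). Pou4f3, Chrna9 and Hspa1b had no probe set under those symbols and were not analysed here. The smallest camera adjusted p was 0.48 for supporting cell genes, 0.982 for otic neuron genes, 0.173 for Notch pathway genes and 0.1 for epithelial genes. Among markers of other cell types it was 0.481 for mesenchymal, 0.689 for skeletal and cardiac muscle, 0.657 for melanocyte and glia, 0.455 for macrophage and blood cell and 0.29 for endothelial genes. It was 0.126 for apoptosis, 0.24 for endoplasmic reticulum stress, 0.817 for glycolysis and 0.782 for cholesterol synthesis genes.

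Other lists passed in some comparisons alone. Early against day 0, the camera adjusted p was 0.101 for otic and inner ear development, 0.354 for ribosomal protein, 0.394 for heat shock and protein folding and 0.527 for oxidative phosphorylation genes. Late against early it was 0.185 for CDK inhibitor and p53 target, 0.448 for interferon and MHC class I and 0.687 for lysosome genes.

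Single members of the lists that passed nowhere changed late against day 0. In the Notch pathway list 2 of 23 probe sets rose, those of Notch3, a receptor (3.88-fold), and Tle5, a Groucho-family protein (3.53-fold). In the otic neuron list, Tubb3, a neuronal tubulin, was 3.72-fold lower and Mapt, the protein tau, 2.64-fold higher. In the apoptosis list 1 of 23 probe sets rose, that of Pdcd4 (3.75-fold), and both probe sets of Cycs, cytochrome c, fell (3.67-fold for the better one). In the glycolysis list 3 of 21 rose and 1 fell, with Ldhb, a lactate dehydrogenase subunit, at least 3.39-fold higher. In the mesenchymal cell list 4 of 19 fell, those of Acta2, Vim and Cd44 among them, and that of Dcn rose. In the endoplasmic reticulum stress list 2 of 23 rose and 2 fell, with Ddit3, a transcription factor gene, at least 2.83-fold higher and Asns, asparagine synthetase, 3.32-fold lower. In the supporting cell list Cdkn1b rose, on 1 of its 3 probe sets, and Vim fell, and in the epithelial list 1 of 20 fell, that of Krt18. These genes were picked for mention after their values were seen. Some lists that did not pass with all arrays passed without 1 culture or under another setting. The list of genes of otic and inner ear development passed early against day 0 without day 0 of experiment A (adjusted p = 0.0423 against 0.101) and with the lower floor (0.0446), and the ribosomal protein list without day 0 of experiment B (0.00157) and in experiment A alone (0.000887), lower in each. Oxidative phosphorylation genes passed late against day 0 without days 0 (0.0236), 8 (0.0267) or 9 (0.0221) of experiment A and with the filter on 8 arrays (0.0403), against 0.0621 with all arrays. These calls were for a decrease of oxidative phosphorylation genes and for an increase of otic and inner ear development genes. Late against early, CDK inhibitor and p53 target genes (0.00243 against 0.185) and epithelial genes (0.033) passed as lower without day 1 of experiment A. Endoplasmic reticulum stress genes passed as higher without day 2 of experiment B (0.0456) or with the Gapdh control ratio as a covariate (0.0463). Relative to day 0, the median of the p53 target list in experiment A was 0.774 on day 3. It was 0.673, 0.419, 0.194 and 0.03 on days 8, 9, 11 and 14. In experiment B it was 1.23 on day 2 and 0.905 on day 9.

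The time course asks which genes followed a smooth curve over all 12 days. Aldh1a1 had the smallest adjusted p (7e-08), with a mean intensity of 313 at day 0 and 8540 late, followed by Gas1 (2.23e-07; 283 and 6490) and Dcn (2.57e-06; 198, the floor, and 14300). Gstm1, a glutathione transferase (749 and 5510), Tmem59, a transmembrane protein of the Golgi (971 and 4320), Col6a1, Gstm2, Ypel3 (850 and 3390), Bmp4 and Fn1 (3060 and 955) made up the rest of the 10 genes with the smallest p, with adjusted p from 6.87e-06 to 1.69e-05. Among the early arrays Gstm1 stood apart at day 3 of experiment A, at a log2 intensity of 11.7. Among the middle arrays Ypel3 stood apart at day 4 of that experiment, at 11.5. Both were near the neighbouring day of the next or previous phase, with intensities of 3277 at day 3 and 3879 at day 4 for Gstm1. For Ypel3 they were 2972 at day 3 and 2845 at day 4. The spline test called 752 of 7726 probe sets, 1241 with experiment as a block and 466 without day 0 of experiment B, and 1776 had an unadjusted p under 0.05. All 10 named genes kept their call whichever culture was left out.

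**Figure D2:**
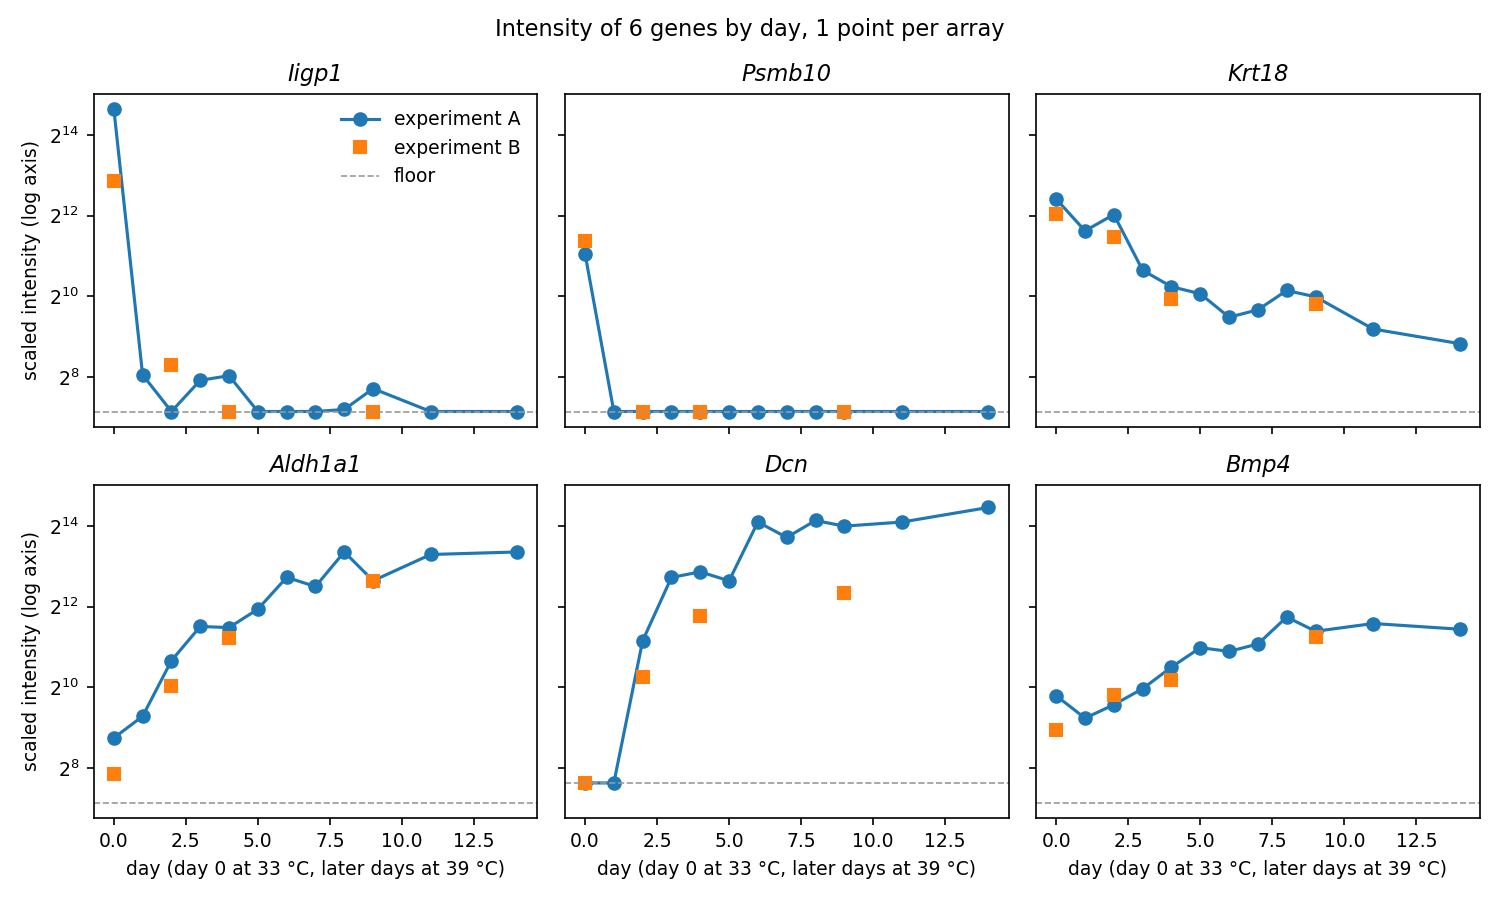
Scaled intensity (vertical log axis) of 6 genes against the day (horizontal axis), 1 point per array, with a line for experiment A, squares for experiment B and a dashed line for the floor. Psmb10 is at the floor, 141, on all arrays after day 0, and Aldh1a1 rises from a day 0 mean of 313 to a late mean of 8540.

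Days 2, 4 and 9 have an array from each experiment, so they can be set against day 0 with n = 2 against 2. By day 9, Iigp1 had fallen 80.6-fold (-6.33 ± 0.71, adjusted p = 0.0167), Psmb10 at least 16.9-fold (adjusted p = 0.00824), Igtp 14.7-fold, Psmb9 at least 10.7-fold and Hmga2 at least 9.26-fold (adjusted p = 0.0075). Dcn had risen at least 46.4-fold (adjusted p = 0.0375), Aldh1a1 20.4-fold (adjusted p = 0.00992), Gas1 19.7-fold, Col6a1 at least 17.4-fold and Crip2 12.5-fold. Day 2 gave 45 changed probe sets (22 higher and 23 lower; 165 with experiment as a block), day 4 140 (78 and 62; 345) and day 9 208 (109 and 99; 525), and 809, 1027 and 1135 had an unadjusted p under 0.05. After quantile normalization day 2 kept 11, with 4 higher and 7 lower. The balance of directions turned on single arrays. At day 9 it was 91 higher and 260 lower without day 0 of experiment B, and 41 and 102 without that of experiment A. It was 120 and 32 without day 9 of experiment A, and 78 and 23 without that of experiment B. Without day 0 of experiment B it was 54 and 227 at day 2 and 79 and 256 at day 4, and without day 2 of experiment B it was 366 and 86 at day 2.

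These day counts depended on single arrays, with 4 residual degrees of freedom in the fit. Without experiment A at day 4 limma called 0 probe sets at day 2 (686 at an unadjusted p under 0.05), 0 at day 4 (723) and 3 at day 9. Day 2 also gave 0 without experiment A at day 9 (792), experiment B at day 4 (690) or experiment B at day 9 (792), and gave 94 without day 0 of experiment A, 281 without day 0 of experiment B and 452 without day 2 of experiment B. Day 4 gave 14 without day 9 of experiment A, and 335, 10 and 18 without days 0, 4 and 9 of experiment B. Day 9 gave 351, 3 and 101 without days 0, 4 and 9 of experiment B. Of the 10 named genes at day 9, Hmga2 alone kept its call whichever array was left out, Crip2 and Dcn lost it in 8 of 8 such fits (largest adjusted p = 0.136 for each, without day 0 of experiment A), Col6a1 (0.13), Igtp (0.152) and Iigp1 (0.103) in 7, Psmb9 (0.16) in 6, Gas1 (0.108) in 5, Aldh1a1 (0.057) in 3 and Psmb10 (0.0509) in 2. After day 0, Hmga2 was at or next to the floor on all arrays of this fit (198 to 207), so its calls rest on values with almost no spread. Psmb10 was at the floor on all arrays after day 0. Without day 9 of experiment A and of experiment B in turn, Dcn was at least 26-fold and 82.7-fold and Col6a1 at least 11.1-fold and 27.3-fold higher. Without day 0 of each, Iigp1 was 43.4-fold and 150-fold lower. The calls at day 9 also ended for Igtp with the lower floor (adjusted p = 0.0812), for Col6a1 with the higher floor (0.057) and the noise covariate (0.0698), and for Dcn with the noise covariate (0.0662).

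The experiments were compared through the log2 change of each probe set from day 0 of its own experiment, across 7726 probe sets, which are not independent replicates. Pearson's r between experiments A and B was 0.582 at day 2, 0.661 at day 4 and 0.517 at day 9, and Spearman's correlation was 0.461, 0.547 and 0.382. Of the probe sets with a change in both experiments, 70.7%, 73.1% and 64.4% moved in the same direction. Iigp1, Psmb10, Hmga2, Aldh1a1 and Gas1 and all other probe sets called at day 2, 4 or 9 had the same direction in both experiments (45 of 45, 140 of 140 and 208 of 208), which the test itself favours. The first principal component of all arrays held 36.6% of the variance and the second 18.4%. The first separated the experiments, with scores of -61.1 to -22 in experiment B and -5.6 to 41.5 in experiment A. The noise level was 68 to 159.8 in experiment B and 103 to 204 in experiment A on design a, and 75 to 160 against 153 to 325 on design b.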

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

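All the tests of this part were chosen with their expected outcome before their result was seen, except the test of a lost interferon stimulus, which was chosen after. The patterns themselves had been seen. In groups of 4 to 10 arrays of a phase, an array was picked out when its gap to the nearest other array was large against the range of the group (Dixon's 95% critical value). This happened in 11 of 117 groups. The critical value is set so that chance flags about 1 in 20 groups of independent values without a trend. Arrays of a phase come from successive days and from both experiments, and the groups share arrays. The share that chance would flag here is therefore not known.

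Interferon and MHC class I genes were lower at 39 °C than at day 0, and a biologist would want to know whether the floor, the noise of the arrays or the culture explains it. The tables argue against the floor and the scale, since over 4 settings of them the largest camera adjusted p of the list late against day 0 was 2.09e-09. With the noise level as a covariate the camera adjusted p of the list was 1.07e-10, but the noise level also differed between the experiments. This fit therefore cannot fully separate noise from experiment. Loss of an interferon stimulus at the change of growth conditions stays open: lines with the same kind of temperature-sensitive immortalizing gene are commonly grown with interferon gamma at 33 °C, and whether these cultures had it is not given in the sources used here. In the 15 probe sets of the list that fell, the single array of day 1 already had 58% of the late change (-1.69 against -2.91). For the 28 fallen cell cycle probe sets it was 41.9%. Psmb10, Gbp3 and Mybl2 were at the floor on day 1 and on every late array, so the floor can affect both shares. A large early share is what a lost stimulus would give, but it was tested on the data that raised the idea. Differentiation itself was not set against it.

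Ribosomal protein genes were lower late than early by a median of -0.43, although with an estimated correlation the list had an adjusted p of 0.0758. A fall of all bright probe sets alike is argued against, since of 10000 random lists matched on level the 2.5th percentile of the median was -0.13. With the Gapdh control ratio as a covariate the camera adjusted p was 1.95e-16, and with the noise level 1e-15. The Gapdh ratio was 0.76 to 0.86 in experiment B and 1.05 to 2.65 in experiment A on design a. On design b it was 0.8 to 0.89 against 0.99 to 2.56. This covariate separates the experiments, and the noise level also differed between them. These fits therefore cannot tell RNA integrity or noise apart from experiment, and both stay open. A biological change during the time at 39 °C stays open as a hypothesis found and tested on the same data.

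The count of 76 changed probe sets late against early was set against other ways to split the same 9 arrays. Of 100 drawn splits of 126 possible ones, 1 had as many calls, the real one, and the highest other count was 12. Among the 58 splits with an array of experiment B in each group it was also 12. This argues against an arbitrary division of the arrays as the source of that count.

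On design a, day 6 of experiment A stood apart among the middle days, with a Gapdh 3' to 5' ratio of 2.65 (nearest 1.18) and a beta-actin ratio of 1.89 (nearest 1.24). On design b it was not picked out, but it also had the highest ratios of the middle days. They were 2.56 for Gapdh (nearest 1.42) and 1.5 for beta-actin (nearest 1.16). Among list medians against day 0, the cell cycle list stood apart late at day 9 of experiment B, at -0.994 (nearest -1.22). The interferon list stood apart late at day 9 of experiment A, at -0.814 (nearest -0.647), and the ribosomal protein list in the middle phase at day 4 of experiment B, at -0.65 (nearest -0.339). These medians are against the mean of both day 0 arrays. Against day 0 of its own experiment, day 4 of experiment B had the smallest ribosomal fall of the middle days, at -0.357 beside -0.6 to -0.525 in experiment A. The interferon list at day 9 of experiment A was then at -1.004, beside -1.023 at day 14. The cell cycle list at day 9 of experiment B was at -1.056, beside -1.185 to -1.093 late in experiment A. In log2 intensity, Cdkn1a stood apart at day 9 of experiment B, at 9.86 (nearest 7.89), Pcna at day 11 of experiment A, at 8.45 (nearest 9.32), and Dcn at day 9 of experiment B, at 12.3 (nearest 14). B2m stood apart at day 4 of experiment B, at 12.7 (nearest 13.9), Gstm1 at day 3 of experiment A, at 11.7 (nearest 10.5), and Ypel3 at day 4 of experiment A, at 11.5 (nearest 11.7). Control probe sets that read the opposite strand were outside all comparisons and above the floor on all 16 arrays. For beta-actin their median intensity was 379.5 on design a and 602 on design b, and for Gapdh 314.5 and 475.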

How the results depend on the processing

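None of the 20 list tests that passed turned direction under any setting. Late against day 0, counts stayed within 1.5 times of 844 except in experiment A alone (555) and without day 0 of experiment B (402). With experiment as a block, the counts were 1241 for the time course, 469 for early and 1117 for late against day 0, 184 for late against early, and 165, 345 and 525 for days 2, 4 and 9. In experiment A alone, early against day 0 gave 173 and late against early 31, with fewer arrays. Early as days 1 and 2 gave 172. Among named genes, calls ended for 27 in experiment A alone, 13 with no filter, 11 with the higher and 7 with the lower floor, 6 on the arcsinh scale and 4 after quantile normalization. With the noise level as a covariate, early against day 0 gave 451 and late against early 166, and with the Gapdh ratio late against early gave 141 and days 2, 4 and 9 156, 354 and 521, both chosen after seeing the data. With no filter late against early gave 40 and day 2 gave 78. Day 2 gave 11 after quantile normalization, 17 with the filter on 8 arrays, 17 on the arcsinh scale and 78 without trend and robust. With the lower floor, days 2, 4 and 9 gave 6, 76 and 115, and r between the experiments was 0.509, 0.582 and 0.393, and with the higher floor r at day 9 was 0.626. Camera with an estimated correlation left 7 list tests. Leaving out each culture in turn gave 466 to 931 for the time course, 126 to 338 for early against day 0, 402 to 929 for late against day 0, 30 to 118 for late against early, 0 to 452 for day 2, 0 to 335 for day 4, 3 to 351 for day 9 and 18 to 22 list tests. Where a single array of a day or phase was left, it was assumed to vary like the other groups. Without day 6 of experiment A, the time course gave 766 and late against early 76. For these changes the cause was not tested. Signal over background limits the dim genes, since at most 50.7% of the probe sets of design a and 40.4% of those of design b were above the floor.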

Other observations

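The camera tests of the nucleolar and glutathione lists described here were chosen, with their expected outcome, after single members had been seen to change and before the lists were tested. Their p-values are adjusted over these 6 tests.

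Genes of ribosome biogenesis in the nucleolus fell with the shift to 39 °C. Gar1, of the box H/ACA particles that modify ribosomal RNA, was 6.58-fold lower late than at day 0, Fbl, the methyltransferase fibrillarin, 6.39-fold, Mybbp1a, a nucleolar Myb-binding protein, 5.59-fold and Ncl, nucleolin, 3.93-fold lower. Without the members noticed first, 12 of 37 probe sets fell late and 0 rose, with a median of -0.94 (camera adjusted p = 1.44e-12, from 4.81e-13; adjusted p = 4.7e-05 with an estimated correlation). Gar1 was not left out and was among these 12, although it had been named before among the largest early decreases. Early against day 0 the median of the same 37 probe sets was -0.80 (camera adjusted p = 7.39e-16). Of them 9 fell, Gar1 again included. Late against early 0 changed (camera adjusted p = 0.208). A coordinated fall of this group early at 39 °C is a hypothesis from these data.

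Genes of glutathione metabolism held several increases late against day 0, such as Gstm2 (9.49-fold), Gstm1 (7.36-fold) and Nfe2l2 (6.45-fold), the transcription factor Nrf2. A coordinated rise of Nrf2 targets beyond those noticed first was not shown late against day 0 (camera adjusted p = 0.145, from 0.0965; adjusted p = 0.349 with an estimated correlation). Of 27 such probe sets, those of Gstm5 (3.62-fold) and Cat, catalase (3.18-fold), rose and that of Gsto1 (3.53-fold lower) fell. Late against early, where 0 of 27 passed, the list rose (camera adjusted p = 0.0202; adjusted p = 0.226 with an estimated correlation).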
